A study of Homo sapiens with 9 samples.

How the data were processed

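RNA was measured in 9 libraries of HEK293T cells, a human embryonic kidney line that takes up plasmids readily. The labels put 3 libraries in each of 3 groups. Cells of the TEAD2 group received Flag-tagged TEAD2 and an empty HA vector, cells of the KR group received the Flag-tagged TEAD2 mutant labelled KR and the empty HA vector, and cells of the SIRT4 group received Flag-tagged TEAD2 and HA-tagged SIRT4. By convention KR stands for lysine replaced by arginine, and the labels name no residue. Per the labels' protocols, plasmids were delivered with polyethylenimine for 6 h, cells were then cultured for 48 h, RNA was taken with Trizol, and 3 ug of total RNA went into each library for a NovaSeq sequencer. Nothing in the labels says that the 3 libraries of a group came from separate cultures, so the p-values measure the spread between these libraries, which may be technical.

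The deposited values are raw counts of reads per gene name. Per the file headers, the authors counted reads over exons with featureCounts 2.0.0 and the GENCODE 38 annotation, summed by gene name, with no option set for strand, read pairs, multiply placed reads or reads that overlap several genes. The submitters' processing notes name SAMtools, featureCounts and the hg38 build. The aligner, any trimming and the way rRNA was handled are not given in the sources used here. Counting without strand means that the count of a gene may include reads from an antisense or divergent partner. Genes with near-identical copies, such as histones, ribosomal proteins, keratins and HSPA6, rest on the reads that were placed uniquely. Reads from a plasmid and from the endogenous gene were counted together for TEAD2 and SIRT4. All 37 genes of the mitochondrial genome had 0 counts in every library, so nothing is said here about mitochondrial transcripts.

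Totals ran from 26463229 to 33085617 counts per library over 59385 gene names, of which 27732 to 29821 had a count in a given library. Counts were filtered with filterByExpr in edgeR 4.0.16 under R 4.3.3, with a minimum count of 10 and a minimum total of 15, which left 20568 genes. They were scaled by TMM and fitted with a robust quasi-likelihood model with 1 mean per group over all 9 libraries and 6 residual degrees of freedom. Each of the 3 comparisons was a two-sided contrast of this fit. Every adjusted p of a gene is from that edgeR test after Benjamini-Hochberg adjustment over all genes tested, with a threshold of 0.05. The common biological coefficient of variation was 0.0954. CPM values use the TMM library sizes, the SE of a fold change is its size divided by the root of the F statistic, and intervals are at the 95% level. Positions are those of the deposited files on hg38.

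Before the data were examined, 34 gene lists were written from general knowledge, and the design, the alternatives and the rule for named genes were fixed. Of these lists, 33 had the 5 tested members required for a set test. The list of mitochondrial genome genes had 0 tested members. Lists were tested with camera in limma 3.58.1 at a preset correlation between genes of 0.01, with adjustment over the 99 tests of the family, and again with an estimated correlation. The fry test, also planned and adjusted over the 99 tests, asks whether a list moved in a common direction. It does not ask whether the list moved more than other genes, or whether members moved in both directions. Fry is given below only for some lists against TEAD2 whose camera call was lost with an estimated correlation. Other lists with a lost call also passed fry, such as interferon-stimulated genes in SIRT4 against KR (fry adjusted p = 0.003) and the wider YAP list in SIRT4 against TEAD2 (0.00435). Some did not, such as ribosomal proteins in SIRT4 against KR (0.424) and the respiratory chain in SIRT4 against TEAD2 (0.24). Counts of list members past the threshold are given over all genes and adjusted over the list alone. The genes named are TEAD2 and SIRT4; the 6 with the largest rise and the 6 with the largest fall in each comparison among genes past the threshold, with a mean log2 CPM of at least 1, a symbol that is not a clone name and groups that do not overlap; 6 YAP targets (CCN1, CCN2, ANKRD1, AMOTL2, AXL and LATS2) whatever their result; and, of each list described, up to 4 members with the smallest p. A few others are marked as chosen after their values were seen.

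The KR and SIRT4 comparisons share the TEAD2 libraries, so the correlation of fold changes that arises without an effect was simulated 20 times with unchanged groups. Each gene was drawn independently, so the simulation leaves out trends over many genes within a library, such as that on GC content. The test was checked on simulated counts of 19959 genes. For KR against TEAD2, 98 genes were changed 1.5-fold and 95 were changed 2-fold. For SIRT4 against TEAD2 the numbers were 97 and 99, and for SIRT4 against KR 192 and 193. For KR against TEAD2 the test recovered 57.1% of genes changed 1.5-fold and 67.4% of those changed 2-fold. Of its calls 8.4% were false. For SIRT4 against TEAD2 these values were 54.6%, 66.7% and 7.03%, and for SIRT4 against KR 58.3%, 65.8% and 4.02%. Against TEAD2 the false shares were above the adjusted p threshold. The real comparisons called 16.1%, 22.3% and 3.79% of genes, in the same order. Recovery and false shares depend on how many genes change. These rates were therefore not shown to hold for the real calls. No pair of libraries of a group agreed within counting noise, since chi-square per gene was at least 6.04 in each pair. The alternatives were size factors by the median of ratios, the DESeq2 1.42.0 Wald test, limma-voom, no filter or a stricter one, a fit of only the groups compared, a replicate block, a test against a 1.2-fold change (glmTreat), the counts without transfected genes, and each library left out in turn. A fit with each library's trend on transcript GC content as an offset was chosen after seeing the data. It covered 17662 genes, 85.9% of those tested, with GC content taken from the GENCODE 29 transcripts. Figures were drawn with matplotlib 3.10.9.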

Results

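The transcriptome of HEK293T cells was compared between 3 groups of 3 libraries that differed in the transfected TEAD2 and in the presence of SIRT4. TEAD2 is a DNA-binding partner of the coactivator YAP, and SIRT4 is a sirtuin, a family of NAD-dependent deacylases. The series addresses whether acetylation of TEAD2 matters for the YAP-TEAD complex, with a KR mutant and SIRT4 as the means to alter it. No library of cells without the TEAD2 plasmid was analysed here, so every value is relative to cells that already made extra TEAD2. The TEAD2 libraries held 26598614 to 31175277 counts, the KR libraries 30875962 to 33085617 and the SIRT4 libraries 26463229 to 29357448. The first principal component of log2 CPM held 24.3% of the variance and separated the 3 groups, with the KR libraries between the others, and the 3 libraries of a group are not stated to come from separate cultures. Libraries also differed in their trend on the GC content of transcripts. The slope of log2 CPM per 10 points of GC ran from -0.12 to 0.012 in the TEAD2 libraries, from -0.016 to 0.1 in the KR libraries and from -0.056 to 0.047 in the SIRT4 libraries.

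**Figure D1:**
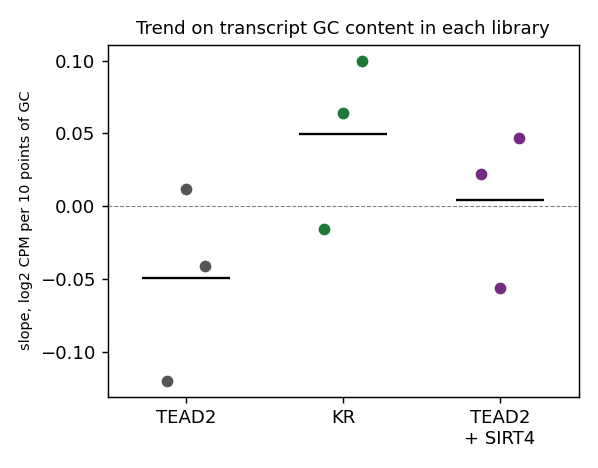
Slope of each library's log2 CPM, relative to the mean of all libraries, per 10 points of transcript GC content; points are libraries and bars are group means (n = 3). Slopes spread within groups, with TEAD2 replicate 1 at -0.12 and TEAD2 replicate 2 at 0.012, and the TEAD2 and KR groups overlap.

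The transfected genes differed in level between the groups. TEAD2 (chromosome 19, 49340595 to 49362457, minus strand) took 0.94% ± 0.0927 (SD, n = 3) of all counts in the TEAD2 group, 0.685% ± 0.0555 in the KR group and 0.269% ± 0.0173 in the SIRT4 group. Against the TEAD2 group its log2 fold change was -0.53 ± 0.07 (SE) in the KR group (edgeR adjusted p = 9.93e-06) and -1.82 ± 0.07 in the SIRT4 group (edgeR adjusted p = 3.02e-15). SIRT4 (chromosome 12, 120302316 to 120313249, plus strand) took 4.89% ± 0.247 of counts in the SIRT4 group, with a log2 fold change of 10.40 against TEAD2 (edgeR adjusted p = 0.00122) and 12.05 against KR (edgeR adjusted p = 0.00552). TEAD2 replicate 1 held 2639 SIRT4 counts, or 88.3 CPM, against 8.34 to 15 CPM in the other 5 libraries without the SIRT4 plasmid. Without this library the fold change of SIRT4 against TEAD2 was 12.22 on the log2 scale. Plasmid and endogenous reads could not be separated for either gene.

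KR against TEAD2 asked what the mutant changes relative to TEAD2 itself. Of the 22 listed YAP-TEAD targets 4 fell, 3 rose and 15 did not pass. CCN1 (chromosome 1, 85580761 to 85584589), a secreted matricellular protein, went from 213 ± 13.2 CPM to 66.5 ± 4.34 (SD, n = 3), a log2 fold change of -1.68 (edgeR adjusted p = 1.94e-14). CCN2, its close relative, had a log2 fold change of -1.14 (edgeR adjusted p = 4.28e-07), and ANKRD1, an ankyrin repeat protein, of -1.75 (edgeR adjusted p = 3.39e-13). GADD45A, a stress-induced growth arrest gene, went from 581 ± 32.6 to 253 ± 27.5 CPM (SD, n = 3, edgeR adjusted p = 1.43e-11). Among genes with a mean log2 CPM of at least 1 and groups that did not overlap, the largest fall was that of INHBA, the activin A subunit, at -2.30, and the largest rise that of C2CD4A, at 1.70. FRMPD2 rose by 1.39, OGFRP1 and BTBD19 each by 1.35 and TMEM167B-DT by 1.25, ZNF804A went from 2.71 ± 0.275 to 6.71 ± 0.691 CPM, while DLGAP1-AS2 stood at -1.74, the carboxypeptidase CPA4 at -1.56 and CYB5R2 at -1.52. Reads were counted without strand, so the counts of TMEM167B-DT and DLGAP1-AS2 may include reads from their neighbours on the other strand. CCN1, CCN2 and ANKRD1 were fixed for naming whatever their result. For each the highest of the 3 KR libraries lay below the lowest of the 3 TEAD2 libraries, a separation in either direction that chance gives for 10% of genes. In all, 1536 genes were higher and 1775 lower at an adjusted p below 0.05, and 213 of them differed at least 2-fold.

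The 22-gene list of YAP/TAZ-TEAD targets did not move as a unit. CCN1, CCN2, ANKRD1 and GADD45A fell, while ARHGEF17, DOCK5 and PTPN14 rose, the last 3 named after their values were seen. Adjusted over the list alone, 4 members were higher and 4 lower. AMOTL2 had a log2 fold change of 0.23 (95% interval 0.01 to 0.44), AXL of 0.43 (-0.01 to 0.88) and LATS2, a Hippo kinase, of 0.04 (-0.17 to 0.26), none past the threshold. The camera test put the list lower (adjusted p = 0.00231), but its median was 0.06 and its mean -0.12, and the call was lost at adjusted p = 0.15 with an estimated correlation. By fry the list was lower (adjusted p = 0.0037). Of 37 Hippo pathway components 6 were higher, among them the YAP-binding AMOT at 0.46, MAP4K4 at 0.41, DLG5 at 0.50 and NF2 at 0.42, and 2 were lower (9 and 4 adjusted over the list alone), MOB1A at -0.26 and MOB1B at -0.56, both named after their values were seen. The list as a whole did not pass the camera test (adjusted p = 0.202).

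Genes of the integrated stress response and of the unfolded protein response were lower as lists in the KR group, and heat shock genes were not. Of 27 genes of the integrated stress response and ATF4, 16 fell and 1 rose (19 and 1 adjusted over the list alone). Among those that fell were ASNS, asparagine synthetase, at -1.08, CEBPG, a bZIP partner of ATF4, at -0.84, SLC7A11, the cystine transporter, at -0.81 and CTH at -0.61, and the member that rose was the stress cytokine GDF15, at 0.89, named after its value was seen. Of 22 genes of the endoplasmic reticulum unfolded protein response, 10 fell and 1 rose (10 and 2 adjusted over the list alone), led by the chaperone HSPA5 at -1.14, HERPUD1 at -0.88, XBP1 at -0.52 and HSP90B1 at -0.52. The member that rose was CRELD2, at 0.37, named after its value was seen. Of 21 heat shock genes 4 rose, with HSPA1B at 0.35 and DNAJA1 at 0.33, and 4 fell, with CHORDC1 at -0.43 (6 and 5 adjusted over the list alone, camera adjusted p = 0.654). The immediate early genes split, with ATF3 at -1.33, JUN at -0.95 and KLF6 at -0.66 among 6 that fell and BTG2 at 0.47 among 3 that rose (7 and 3 adjusted over the list alone). Of the 20 genes on the list of p53 targets 9 rose and 0 fell (11 and 0 adjusted over the list alone). Examples are PHLDA3 at 0.69, BAX, a mediator of apoptosis, at 0.54, SESN1 at 0.50 and the repair gene XPC at 0.48. These counts depend on how genes were assigned to lists. GADD45A and ATF3, which fell, were counted in other lists and not in this one. Ribosomal protein genes fell in 23 of 46 cases and rose in 0 (30 and 0 adjusted over the list alone), with RPS25 at -0.54 and RPL14 at -0.35.

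The camera adjusted p was 2.02e-16 for the integrated stress response, 9.45e-09 for the unfolded protein response and 5.2e-06 for p53 targets, and each of these held at adjusted p = 0.0395 with an estimated correlation. Ribosomal proteins (camera adjusted p = 7.78e-12) were lost at adjusted p = 0.615 with an estimated correlation, and immediate early genes (camera adjusted p = 0.0328) at adjusted p = 0.619 with an estimated correlation. Neither list passed fry (adjusted p = 0.0907 and 0.116). The immediate early call was also lost without TEAD2 replicate 2 (adjusted p = 0.0874), TEAD2 replicate 3 (0.082) or KR replicate 1 (0.109). Fold changes in this comparison rose with GC content over all genes (Spearman 0.28 across genes, which are not independent replicates): of 5 equal bins of genes by GC content, the lowest held 794 genes that fell and 99 that rose, and the highest 96 that fell and 485 that rose. With each library's trend removed, a setting chosen after seeing the data, 2656 of the 3365 calls among genes with a GC value were kept. The integrated stress response then had 21 members lower and 1 higher, the unfolded protein response 10 and 1, ribosomal proteins 27 and 0, and p53 targets 2 lower and 11 higher. The count of 3311 genes became 1988 without KR replicate 2 and 2200 without TEAD2 replicate 1, and 488 genes exceeded a 1.2-fold change in the glmTreat test. The 1536 higher genes became 815 without KR replicate 2, 883 without TEAD2 replicate 1 and 993 without TEAD2 replicate 3.

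SIRT4 against TEAD2 asked what SIRT4 changes in cells with the same TEAD2 plasmid. The same 4 YAP-TEAD targets fell here: CCN1 had a log2 fold change of -1.77 and stood at 62.3 ± 5.32 CPM (SD, n = 3), CCN2 was at -1.44, ANKRD1 at -1.52 and GADD45A at -1.17, with edgeR adjusted p = 3.02e-15 for CCN1 and 7.04e-09 for CCN2. HSPA6, an inducible heat shock protein, had the largest fall of the named genes, at -3.47, from 9.18 ± 0.531 to 0.817 ± 0.278 CPM (SD, n = 3, edgeR adjusted p = 9.38e-12). INHBA stood at -2.37, the basal keratin KRT14 at -2.14, CYB5R2 at -2.03, the fucosyltransferase FUT1 at -1.95 and CPA4 at -1.91. HSPA6, KRT14 and histone genes have near-identical copies, so their counts rest on the reads that were placed uniquely. The adaptor CASS4 rose by 1.99, the histone gene H3C6 by 1.90, LRRC46 by 1.78, TAF7L by 1.76, NPC1L1, a sterol transporter, by 1.70 and ZNF425 by 1.68. In all, 2306 genes were higher and 2277 lower, 453 of them at least 2-fold.

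**Figure D2:**
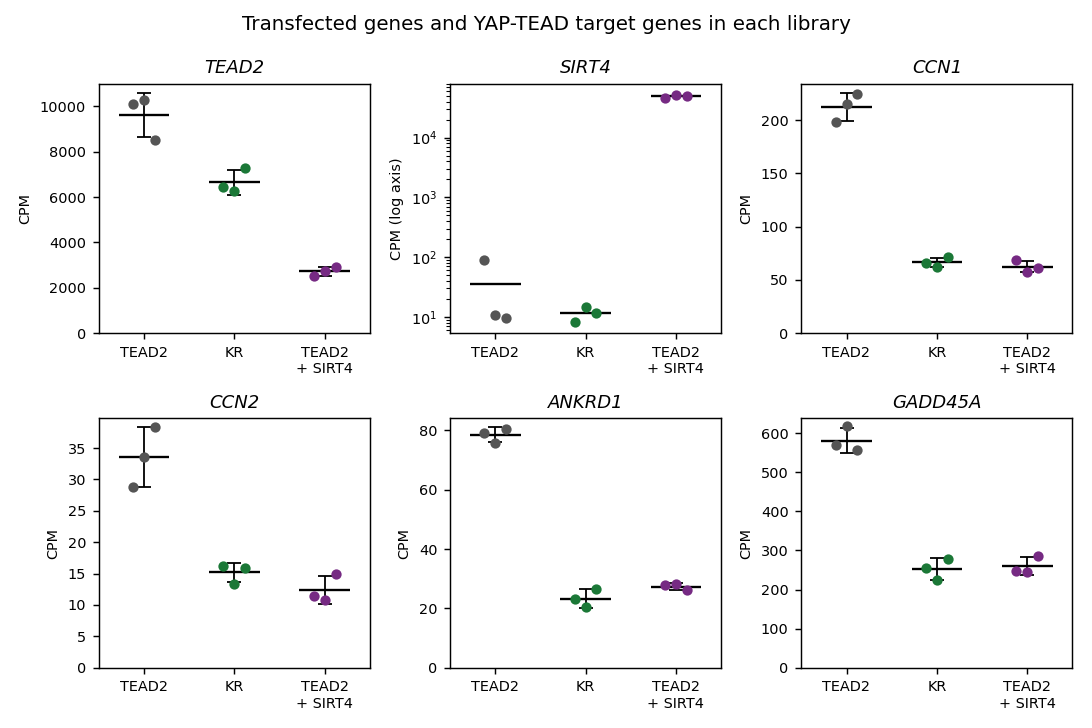
CPM of TEAD2, SIRT4 and 4 YAP-TEAD targets in each library by group; points are libraries, bars are means and whiskers are SD (n = 3; not drawn for SIRT4, which is on a log axis). CCN1 averaged 213 CPM in the TEAD2 group, 66.5 in the KR group and 62.3 in the SIRT4 group.

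Among the other YAP/TAZ-TEAD targets, AMOTL2 rose by 0.56 and AXL by 0.62 in the SIRT4 group, as did ARHGEF17, by 0.39, and IGFBP3, by 1.28 (both named after their values were seen), so that 4 of 22 members were higher and 4 lower (5 and 4 adjusted over the list alone). The call of AXL, at 4.43 ± 0.543 CPM, was lost without TEAD2 replicate 2 (edgeR adjusted p = 0.175), TEAD2 replicate 3 (0.0771), SIRT4 replicate 1 (0.159) or SIRT4 replicate 2 (0.0789), and with no low-count filter (0.0627). LATS2 had a log2 fold change of 0.08 (95% interval -0.14 to 0.29). The list was lower by camera (adjusted p = 0.000302), with a median of -0.05 and a mean of -0.19, a call lost at adjusted p = 0.115 with an estimated correlation. By fry it was lower (adjusted p = 0.00174). Of 37 Hippo components 8 were higher, with NF2 at 0.57, MAP4K4 at 0.50 and TAOK2 at 0.47, and 3 were lower, with MOB1A at -0.37 (10 and 3 adjusted over the list alone), and the camera adjusted p was 0.27, with a median of -0.01, a mean of 0.03 and a test directed upwards.

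Of the 27 genes of the integrated stress response 21 fell and 2 rose (21 and 2 adjusted over the list alone), led by the glutathione-degrading enzyme CHAC1 at -1.36, CEBPG at -1.12, SLC38A2 at -0.75 and PPP1R15A at -0.66, while GDF15, from 7.95 ± 1.24 to 15.9 ± 1.53 CPM (SD, n = 3), and SESN2, by 0.20, rose, both named after their values were seen. In the unfolded protein response list 10 of 22 fell and 1 rose (11 and 1 adjusted over the list alone), with HERPUD1 at -1.10 and HSPA5 at -0.98. Among 20 p53 targets 15 rose and 1 fell (17 and 1 adjusted over the list alone), with XPC at 0.88, BAX at 0.66, MDM2, the ligase that marks p53 for degradation, at 0.63 and SESN1 at 0.62. The member that fell was BBC3, at -0.37, named after its value was seen. GADD45A and ATF3, which also fell, are not on this list. Transcripts of replication-dependent histone genes lack a poly(A) tail, so their level also varies with how RNA was selected. The selection is not given in the sources used here. These genes rose in 8 of 18 cases and fell in 0 (13 and 1 adjusted over the list alone), with H4C8 at 1.23 and H2BC5 at 1.15. Matrix and adhesion genes fell in 16 of 36 cases and rose in 2 (17 and 2 adjusted over the list alone), with COL12A1 at -0.86, SNAI2 at -0.56 and LAMA1 at -0.56. Of 11 fibroblast markers 3 fell, PDGFRA at -1.03, S100A4 at -0.73 and TWIST1 at -0.55, and 0 rose (4 and 0 adjusted over the list alone), and the list did not pass camera (adjusted p = 0.219). These calls were lost when a library was left out: that of PDGFRA without TEAD2 replicate 1 (edgeR adjusted p = 0.0733), TEAD2 replicate 3 (0.123) or SIRT4 replicate 1 (0.12), that of S100A4 without TEAD2 replicate 1 (0.0518), TEAD2 replicate 2 (0.209) or SIRT4 replicate 2 (0.155), and that of TWIST1 without TEAD2 replicate 2 (0.102). With limma-voom PDGFRA (0.0503) and S100A4 (0.0541) did not pass. Ribosomal protein genes fell in 40 of 46 cases and rose in 0 (43 and 0 adjusted over the list alone), with RPS25 at -0.61. Of 33 interferon-stimulated genes 10 fell, including ISG15 at -0.97 and DDX60 at -0.91, and 4 rose (11 and 5 adjusted over the list alone). In KR against TEAD2 this list had 5 members higher and 4 lower (camera adjusted p = 0.67). DDX60 stood at 54.43 to 69.58 CPM in the KR libraries and 121.5 to 134.6 in the TEAD2 libraries, and ISG15 at 256.7 to 299.1 and 422.9 to 465.2. Immediate early genes fell in 9 of 25 cases, with ATF3 at -1.44, JUN at -1.07 and KLF6 at -0.79, and rose in 4, with BTG2 at 0.72 (9 and 4 adjusted over the list alone).

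The integrated stress response (camera adjusted p = 1.12e-24) and p53 targets (4.3e-13) held at adjusted p = 0.035 with an estimated correlation, and the unfolded protein response (9.45e-09) at adjusted p = 0.0395 with an estimated correlation. Histones (camera adjusted p = 2.99e-05) and matrix genes (0.000209) were each lost at adjusted p = 0.0567 with an estimated correlation, ribosomal proteins (9.65e-18) at adjusted p = 0.482 with an estimated correlation and interferon-stimulated genes (0.0328, list mean 0.00 and median -0.12) at adjusted p = 0.15 with an estimated correlation. By fry histones were higher (adjusted p = 0.000606), and matrix (0.000635), ribosomal protein (0.0273) and interferon-stimulated genes (0.00113) lower. Immediate early genes did not pass fry (adjusted p = 0.0592). Immediate early genes (camera adjusted p = 0.0121, median 0.01, mean -0.06) were lost at adjusted p = 0.564 with an estimated correlation and at 0.0751 without SIRT4 replicate 2, and the interferon call was lost at 0.061 without SIRT4 replicate 1. The SIRT4 libraries also had the lowest TEAD2 level and the most counts from transfected genes, 5.15% ± 0.258 against 0.944% ± 0.0945 in the TEAD2 group (SD, n = 3). Fold changes rose with GC content here too (Spearman 0.13 across genes): of 5 equal bins the lowest held 688 genes that fell and 293 that rose, and the highest 223 and 531. Against a 1.2-fold change 1062 genes passed in the glmTreat test.

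**Figure D3:**
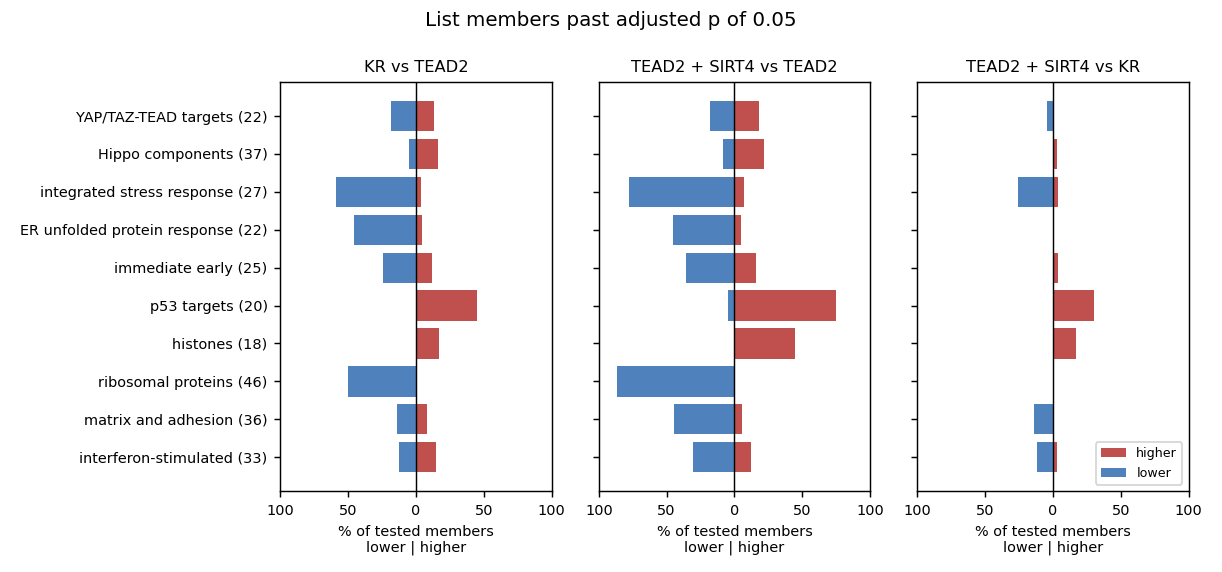
Share of tested members of 10 gene lists past an edgeR adjusted p of 0.05, in percent, lower to the left and higher to the right, for each comparison; the number of tested members stands in brackets. Of 27 integrated stress response genes 16 were lower in the KR group and 21 in the SIRT4 group, and of 20 p53 targets 9 and 15 were higher.

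The responses of the KR and SIRT4 groups overlapped. Of 20566 genes, without TEAD2 and SIRT4, 1013 were higher in both, 1246 lower in both and 7 opposite. Independent lists of these sizes would share 172.2 and 196.3, values that do not allow for the TEAD2 libraries the lists have in common. Against a 1.2-fold change in the glmTreat test 309 genes were shared. Fold changes correlated at 0.654 across genes (simulated with no effect 0.506), with a covariance of 0.154 against 0.0557 in the simulation. Both comparisons use the same 3 TEAD2 libraries, which are too few to split, so part of the excess may come from the shared controls. The simulation drew genes independently and held no trend of a library on GC content. The shared genes were 68.2% of the KR calls and 49.3% of the SIRT4 calls, and 87 of these 2259 genes differed between the KR and SIRT4 groups.

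**Figure D4:**
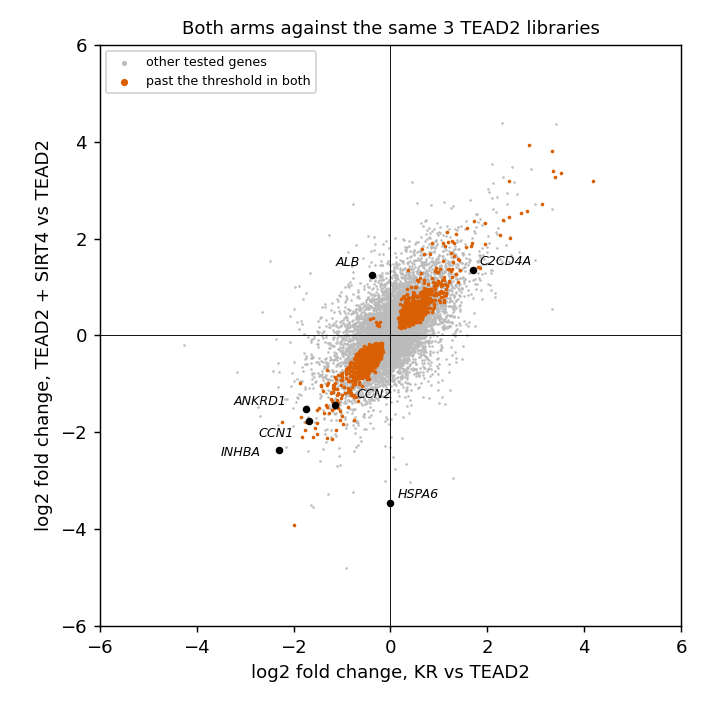
Log2 fold change of each gene in the KR group (x axis) and the SIRT4 group (y axis), each against the same TEAD2 libraries; orange points passed the threshold in both, and 2 of 20566 genes lie outside the axes at 6. CCN1, CCN2, ANKRD1 and INHBA lie low in both, while HSPA6 lies at -3.47 in the SIRT4 group and at 0.00 in the KR group.

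SIRT4 against KR compared these 2 groups directly. HSPA6 fell by 3.46 (95% interval -3.92 to -3.01, edgeR adjusted p = 7.03e-11), and its co-chaperone DNAJB1 fell by 0.64 (edgeR adjusted p = 2.55e-06). TXNIP, a thioredoxin-binding protein that responds to glucose, fell by 0.99 (edgeR adjusted p = 1.59e-07), KRT17 was at -0.85 and CHAC1 at -0.69. CASS4 rose by 1.73, ALB, serum albumin, by 1.63, TF, transferrin, by 1.31, ANPEP by 1.31 and TAF7L by 1.27. CYP4F2 was at -1.32 and C1orf167 at -1.15, TMEM271 went from 3.11 to 1.55 CPM and TMEM52 from 4.39 to 2.20, and PYGM went from 1.47 to 3.39. Without SIRT4 replicate 1 the calls of CYP4F2 (edgeR adjusted p = 0.109), C1orf167 (0.0515), TMEM271 (0.102), TMEM52 (0.187), PYGM (0.167), TF (0.0579) and TAF7L (0.0579) were lost. TF (0.0542), ANPEP (0.0541), CYP4F2 (0.0651), TMEM271 (0.164), TMEM52 (0.155) and PYGM (0.177) were lost without KR replicate 2, ANPEP also without SIRT4 replicate 2 (0.0713), and the calls of CYP4F2, C1orf167, TMEM271, TMEM52 and PYGM without at least 1 further library. In all, 562 genes were higher and 218 lower, 56 of them at least 2-fold, and with DESeq2 715 were higher and 414 lower. Without SIRT4 replicate 3, 364 were lower.

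The YAP-TEAD targets that fell in both groups were not shown to differ between them. The difference SIRT4 minus KR was -0.09 for CCN1 (95% interval -0.25 to 0.06), -0.30 for CCN2 (-0.57 to -0.03), 0.23 for ANKRD1 (0.04 to 0.42), 0.04 for GADD45A (-0.11 to 0.19), 0.33 for AMOTL2 (0.12 to 0.54), 0.19 for AXL (-0.24 to 0.62) and 0.04 for LATS2 (-0.18 to 0.25), with edgeR adjusted p from 0.0715 for AMOTL2 to 0.903 for LATS2. CCN2 passed without SIRT4 replicate 3 (adjusted p = 0.0411), and AMOTL2 with DESeq2 (0.0331) and with the GC trends removed (0.0196). Of the 22-gene list 0 were higher and 1 lower, MYOF at -0.36, named after its value was seen (1 and 1 adjusted over the list alone), with camera adjusted p = 0.219. The call of MYOF was lost without KR replicate 1 (edgeR adjusted p = 0.0964), KR replicate 2 (0.123), SIRT4 replicate 1 (0.134), SIRT4 replicate 2 (0.085) or SIRT4 replicate 3 (0.0504).

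Matrix and adhesion genes fell in 5 of 36 cases and rose in 0 (18 and 0 adjusted over the list alone), with CDH1, E-cadherin, at -0.49, and p53 targets rose in 6 of 20 cases and fell in 0 (8 and 0 adjusted over the list alone), with PLK3 at 0.60, AEN at 0.38 and XPC at 0.40. These lists held at adjusted p = 0.035 and adjusted p = 0.0395 with an estimated correlation. Fibroblast markers were lower along with the matrix list, with a median of -0.265 and camera adjusted p = 0.0225, lost at adjusted p = 0.15 with an estimated correlation and at 0.0754 without KR replicate 3, and 0 of 11 passed singly (1 lower adjusted over the list alone). The integrated stress response had 7 lower and 1 higher, the amino acid transporter subunit SLC3A2 at 0.33 (13 and 2 adjusted over the list alone), with camera adjusted p = 5.13e-06, lost at adjusted p = 0.15 with an estimated correlation. Of 5 liver markers with enough counts, ALB and TF rose, APOA2 was at 0.79 SERPINA1 at 0.97 and AFP at -0.53 without passing the test, and the list's call (camera adjusted p = 0.00203; 2 higher and 0 lower adjusted over the list alone) was lost at adjusted p = 0.173 with an estimated correlation. ALB stood at 4.67 ± 0.794 CPM in the SIRT4 group and 1.51 ± 0.261 in the KR group (SD, n = 3). The count of 780 genes became 326 without KR replicate 2, 339 without KR replicate 3, 337 without SIRT4 replicate 1 and 305 without SIRT4 replicate 2, and 45 genes exceeded a 1.2-fold change in the glmTreat test. Fold changes fell with GC content (Spearman -0.18 across genes), with 201 genes higher and 19 lower in the lowest of 5 bins. With the GC trend of each library removed, 1572 of the genes with a GC value passed, 882 higher and 690 lower. The same genes gave 845 calls without this.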

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

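The fit with GC trends removed was chosen after seeing the data, and all other settings before the data were examined. Against a 1.2-fold change in the glmTreat test the counts of genes fell to 488 for KR against TEAD2, 1062 for SIRT4 against TEAD2 and 45 for SIRT4 against KR, and their overlap to 309, since that test asks for a larger change. With an estimated correlation between genes 3, 3 and 2 lists passed instead of 9, 13 and 13, and the YAP/TAZ-TEAD list had adjusted p = 0.15 and 0.115 against TEAD2. With the GC trends removed SIRT4 against KR had 1572 genes, against 845 over the same genes without this, and the cause was not tested. With 1 library left out in turn, the count for KR against TEAD2 ranged from 1988 (without KR replicate 2) to 3574, and that for SIRT4 against KR from 305 (without SIRT4 replicate 2) to 1043, with 6 (without KR replicate 3) to 18 lists; these fits have fewer samples, and the libraries' part in this was not tested further. Size factors by the median of ratios, DESeq2, limma-voom, both other filters, the fit of only the groups compared, the replicate block and the fit without transfected genes left each total count of genes within 1.5 times its value, but DESeq2 had 715 higher and 414 lower genes in SIRT4 against KR, where 218 were lower. Numbers did not pair the libraries: the block gave 3335, 4536 and 789 genes, and 2 of 9 libraries correlated best with those of their own number. DESeq2 gave no adjusted p for SIRT4 itself. Of 276 calls among 313 named results 0 reversed, 139 were lost with glmTreat, 59 with a library left out and 18 in other settings, and 137 were kept in all 19 settings. Depth was varied only through the filters on low counts.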

Other observations

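Of the tests in this part, all those of the 3 patterns except that of scaling, and the tests of genes named ZNF and of small nucleolar RNA host genes, were chosen only after the result was seen. Several further lists complete the account. In the KR group mitotic genes fell in 8 of 30 cases and rose in 1 (9 and 1 adjusted over the list alone), with TTK at -0.51 and CDK1 at -0.40 (camera adjusted p = 0.0149, lost at adjusted p = 0.508 with an estimated correlation and at 0.109 with the GC trends removed). Histone genes, whose transcripts lack a poly(A) tail, rose in 3 of 18 cases and fell in 0 (3 and 0 adjusted over the list alone), with H2AC6 at 0.94, and camera adjusted p = 0.046 was lost at adjusted p = 0.291 with an estimated correlation and without TEAD2 replicate 2 (0.0517), TEAD2 replicate 3 (0.0826), KR replicate 3 (0.092) or SIRT4 replicate 2 (0.0572), and at 0.0901 with the GC trends removed. Of 9 listed long noncoding RNAs SNHG1, at -0.72, GAS5 and KCNQ1OT1 fell and FTX rose (3 lower and 3 higher adjusted over the list alone). SNHG1 is a small nucleolar RNA host gene. The list was written for RNAs kept in the nucleus, which was not tested here. The camera call of this list (adjusted p = 0.0209) was lost at adjusted p = 0.615 with an estimated correlation. That call was also lost without KR replicate 2 (camera adjusted p = 0.1) or KR replicate 3 (0.0995). The call of KCNQ1OT1 was lost without TEAD2 replicate 1 (edgeR adjusted p = 0.0856), TEAD2 replicate 3 (0.0875), KR replicate 2 (0.159) or KR replicate 3 (0.0771). That of FTX was lost without TEAD2 replicate 2 (edgeR adjusted p = 0.196), TEAD2 replicate 3 (0.148), KR replicate 1 (0.272), KR replicate 2 (0.0668) or SIRT4 replicate 1 (0.056), with limma-voom (0.0608) and with size factors by the median of ratios (0.05). In the SIRT4 group the nuclear-encoded respiratory chain had 11 of 42 genes lower and 2 higher (11 and 2 adjusted over the list alone), with COX6C at -0.55, and the citrate cycle and glutamine list 9 of 30 lower and 2 higher (13 and 3 adjusted over the list alone), with ME3 at -1.28. Their camera adjusted p = 0.0328 was lost at adjusted p = 0.726 and adjusted p = 0.715 with an estimated correlation, and without SIRT4 replicate 2 (0.138 and 0.118) or SIRT4 replicate 1 (0.0516 and 0.0829), and for the respiratory chain without TEAD2 replicate 2 (0.0829). Serum response and cytoskeleton genes had 8 of 23 lower and 4 higher (8 and 4 adjusted over the list alone), with KRT17 at -1.82 and ACTA2, smooth muscle actin, at 1.28. Their median was 0.02 and mean -0.13, with camera adjusted p = 0.0141, lost at adjusted p = 0.644 with an estimated correlation and at 0.0889 without SIRT4 replicate 2. The wider YAP list had 10 of 48 lower and 3 higher (10 and 4 adjusted over the list alone), with ETV5 at -1.17 and DUSP1 at -0.86 (camera adjusted p = 0.0164, lost at adjusted p = 0.15 with an estimated correlation).

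Between SIRT4 and KR, histone genes rose in 3 of 18 cases (4 adjusted over the list alone), with H4C8 at 0.93 (camera adjusted p = 0.000308, lost at adjusted p = 0.088 with an estimated correlation), and heat shock genes fell in 3 of 21 cases and rose in 0 (4 and 1 adjusted over the list alone; camera adjusted p = 0.0328, lost at adjusted p = 0.615 with an estimated correlation and at 0.267 without SIRT4 replicate 1 and at 0.0838 without KR replicate 3). Interferon-stimulated genes had 4 of 33 lower and 1 higher (7 and 1 adjusted over the list alone), with ISG15 at -0.32 (camera adjusted p = 0.00695, lost at adjusted p = 0.088 with an estimated correlation). The lists of ribosomal proteins, glycolysis, TGF-beta, the wider YAP targets and Notch, with 0, 1, 2, 1 and 1 members lower and 0 higher (0, 1, 3, 1 and 1 lower adjusted over the list alone, and 1 higher for YAP), passed camera at adjusted p = 0.000209, 0.00583, 0.00881, 0.0175 and 0.0254, and were lost at adjusted p = 0.725, 0.644, 0.506, 0.15 and 0.615 with an estimated correlation; without KR replicate 3 each was lost too (0.187, 0.0566, 0.0566, 0.0755 and 0.178). Without SIRT4 replicate 2 the calls of ribosomal proteins (0.0508), glycolysis (0.0678), TGF-beta (0.0678) and Notch (0.132) were lost, as was glycolysis without SIRT4 replicate 1 (0.0874) and Notch with the GC trends removed (0.111). Of the 3 comparisons of 33 lists, 9, 13 and 13 passed with the preset correlation. The remaining lists, among them sirtuins, acetyltransferases and deacetylases, cholesterol synthesis, fatty acid oxidation, MYC and ribosome biogenesis, NF-kB, Wnt and markers of blood and of keratinocytes, passed in none, nor did S phase and mitochondrial stress genes (smallest camera adjusted p = 0.0745, for Wnt in SIRT4 against KR). With the GC trends removed S phase genes passed in SIRT4 against KR (camera adjusted p = 0.0183, with 9 of 32 higher and 0 lower, against 4 and 0 without this), and serum response genes in KR against TEAD2 (camera adjusted p = 0.0165, against 0.16 without this). Of genes named ZNF, most of them zinc finger transcription factors, 66 of 517 were higher in SIRT4 than in KR (12.8% against 2.47% of other genes, Fisher's exact test, adjusted p = 8.16e-25 over 12 tests), with 123 higher in SIRT4 against TEAD2 (23.8% against 10.9%, adjusted p = 1.69e-15) and 44 in KR against TEAD2 (8.51% against 7.44%, adjusted p = 0.468). Lower were 55 in KR against TEAD2 (10.6% against 8.58%, Fisher's exact test, adjusted p = 0.192) and 28 in SIRT4 against TEAD2 (5.42% against 11.2%, adjusted p = 3.73e-05). In SIRT4 against KR 4 were lower (0.774% against 1.07%, adjusted p = 0.727). With the GC trends removed the share of genes named ZNF that were higher in SIRT4 against KR was 16.7% against 4.64%. Of 22 small nucleolar RNA host genes 5 were higher in SIRT4 than in KR (22.7% against 2.71%, adjusted p = 0.000804). In KR against TEAD2, 0 were higher and 5 lower (22.7% against 8.61% for lower, adjusted p = 0.0871), and in SIRT4 against TEAD2 4 were higher and 5 lower (adjusted p = 0.452 and 0.176). Fisher's test treats the genes of both families as independent draws, was not repeated with an estimated correlation, and holds no spread between libraries.

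The 3 libraries of each group allow 10 splits, which are too few for a share under 0.05. In each comparison 1 of the 10 splits, the real one, gave as many genes, with 3311 for KR against TEAD2 and at most 0 for the other splits, 4583 and 0 for SIRT4 against TEAD2, and 780 and 134 for SIRT4 against KR.

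CCN1, CCN2, ANKRD1 and GADD45A were lower in both groups, and the TEAD2 transcript was lower too. A fall that follows this transcript at the rate per log2 unit seen in KR predicts a median difference of -3.50 between SIRT4 and KR. A fall by as much as the transcript itself predicts -1.29. The values argue against both: that difference was -0.029, and the largest SE of a single gene among the 4 was 0.131. This SE is not that of the median, and CCN2 and ANKRD1 differed in opposite directions. Both predictions assume that SIRT4 has no other effect on these genes. Scaling stays open, since other size factors or the counts without transfected genes moved the median of the 4 genes by at most 0.008 and that of all genes by at most 0.0085, so this test decided nothing and the falls are relative to the other genes. A response to the lower TEAD2 transcript that does not grow with its fall stays open for both groups, where 0 KR and 0 SIRT4 libraries reached the TEAD2 level of the TEAD2 group, so this and an effect on the acetylation of TEAD2 cannot be told apart. TEAD2 protein and its acetylation were not analysed here.

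The integrated stress response list was lower in both groups. A load of transfected transcript that raises the stress response would put the SIRT4 group highest, as it had 5.15% of counts from transfected genes, but its list median was -0.572 against TEAD2. Most of that load was SIRT4 transcript (4.89%), so load and SIRT4 itself cannot be told apart in this group. The KR group had a lower load than the TEAD2 group, 0.6865% against 0.944%, along with the lower list. Load therefore stays open for KR. GC content and gene length are argued against as the whole source: with their trends and that of expression removed, the median nearer to 0, that of KR, was -0.262, against -0.274 before (95% interval -0.48 to -0.19). This interval came from resampling the 27 list genes, which are not independent replicates, and holds no spread between libraries. The lower TEAD2 transcript of both groups stays open as a source and was not tested, since no cells without the plasmid were analysed here.

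Genes of low GC content were lower in the KR group (Spearman of fold change with GC content 0.28), as to a lesser degree in the SIRT4 group (0.13), with the reverse in SIRT4 against KR (-0.18). GC trends of single libraries are in line with this: slopes within the TEAD2 group ranged 1.31 times as far as the group means lay apart, and the groups overlapped. As the source of most calls they are argued against, since 78.9% of calls were kept with the trends removed. An effect of the mutant on such genes stays open, as 3 libraries cannot separate it from the preparation of single libraries.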
